A study of Sus scrofa with 18 samples.

How the data were processed

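Total RNA from pig masseter (a chewing muscle) and biceps femoris (a thigh muscle) had been hybridised to Affymetrix porcine arrays, 1 array per muscle sample, 18 arrays in all. Per the labels, RNA was extracted with Trizol and RNeasy columns and biotinylated cRNA was made by the Affymetrix protocol. Per the labels, the authors processed the arrays with RMA, which corrects the background, normalizes between arrays and summarises the probes of a probe set as a log2 value. The deposited log2 values of the 18 arrays were used as they stand, between 2.52 and 15.2. A further table deposited by the authors for biceps femoris holds the same log2 values per array, a log2 fold change, an adjusted p-value and a B-statistic, which is a log odds score, per the file headers. A short list deposited by the authors gives the ratio of day 5 to day 1, as a linear fold, for genes over 2-fold in biceps femoris, per the file headers. All per-array columns of the deposited tables entered a comparison.

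The sorted values of any pair of masseter arrays differed by at most 0.230, those of any pair of biceps femoris arrays by at most 0.237, and those of a masseter and a biceps femoris array by at least 0.541. The authors had therefore normalized the muscles apart. The planned test of masseter against biceps femoris at day 1 was not made for this reason, and only changes within a muscle, and differences between such changes, were tested.

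Groups followed the titles and the series text. There were 5 day 1 and 5 day 5 arrays of masseter, and 4 day 1 and 4 day 5 arrays of biceps femoris. The source and treatment labels of the biceps femoris day 1 arrays call them treated, whereas their titles, descriptions and the series text call them controls, which were followed. A breed tag names wild boar, whereas the protocols name domestic piglets. Day 1 and day 5 masseter arrays of 1 number came from 1 animal, per the sample descriptions. The biceps femoris labels share numbers without naming animals. No fit therefore linked both muscles of an animal. The tests of the difference between the muscles took their arrays as independent, which arrays of the same animals need not be. The agreement of the muscles carries the same limit. Same-numbered masseter arrays deviated together from their group means little or not at all (correlations across probe sets from -0.03 to 0.12). Replicates 2 and 4 correlated best with their own number (0.12 each), the others with another number (up to 0.14). The labels name no arrays from animals without the drugs and endotoxin, so the passage of 4 further days and the treatment cannot be told apart.

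Of 24123 probe sets, 124 Affymetrix controls were left out and 23999 tested. Genes were named from the pig annotation table and from the authors' human homolog column, with older symbols updated. In total 19024 probe sets had 1 gene symbol, for 9900 genes, 91 had several symbols and 4884 had none. The homolog named another gene than the pig annotation for 247 probe sets, among them those of MYH4, ISG15, ZXDC, THY1 and ACTN2. Myosin heavy chain genes and members of the 70 kDa heat shock family have near-identical copies that probes may share. Each gene was represented by the probe set with the highest mean over both muscles. No probe set carried the names TRIM63, HSPA1A or HSPA1B, which are not analysed here.

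Each muscle was fitted on its own arrays with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, without covariates, and the difference between the muscles was the contrast of both changes in a fit of all 18 arrays with 4 groups. P-values were adjusted by the Benjamini-Hochberg method over the 23999 probe sets, and an adjusted p under 0.05 counted as a call. Errors of single values are SD between arrays of a group and errors of changes are SE from limma. The correlation of the changes of both muscles was computed across probe sets, which are not independent replicates, so it has no p. Overlaps of calls were set against the number that independent lists would share.

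The tests used 20 gene lists and 7 lists of cell type markers, fixed in advance. They were tested with limma's camera at its preset correlation of 0.01 on 1 probe set per gene, adjusted over the 27 lists of a comparison. No list passed with camera's estimated correlation, and those p-values are given with each list. Members were also counted with p-values adjusted over the list alone. Named genes were chosen by a rule that was also fixed in advance. It took the 8 largest rises and the 8 largest falls per muscle among called genes whose groups did not overlap, the same numbers for the difference without that demand, up to 4 members per list with the smallest p, and a fixed set of muscle genes. After the values were seen, the list members given in the text and put through the alternatives were narrowed to the 2 of smallest p per passing list, with any further member said to be such or taken from those 4. One gene that the rule names is not reported here. Functions of genes given below are background knowledge.

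The fits were tested on simulated data with the spread of the real arrays, in which 200 of 23999 probe sets were changed. Of changes of 1 on the log2 scale, 83.6% were called with the masseter arrays, 68.7% with the biceps femoris arrays and 55.2% for the difference. For changes of 0.5 the shares were 11.9%, 28.4% and 7.46%, and for changes of 2 they were 97.0%, 93.9% and 90.9%. False calls numbered 5 of 133, 7 of 134 and 9 of 111 calls. The real fits within masseter and biceps femoris called many more probe sets (3318 and 4117). More calls ease the adjusted threshold, so the simulated shares need not hold for those fits. A shifted list of simulated genes was called in each comparison, with 0 of 26 other lists. The simulated genes varied independently of each other, so this could not test camera's preset correlation between the genes of a list. The number of arrays limits the precision of every value.

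The groups, lists, rule and these alternatives were chosen before the data were examined. The alternatives were a further quantile normalization, centring of arrays on their medians, leaving out the probe sets in the lowest part of the mean values, eBayes with trend and robust settings, array weights, a 2-fold minimum, a replicate block, 1 fit of all 18 arrays, the authors' table of values, leaving out each array or masseter animal, fry in place of camera, an estimated correlation, and the mean of all probe sets of a gene. Alternatives chosen after seeing the data were a block for a group of biceps femoris arrays set apart by a hybridisation spike-in, and an animal block in masseter alone. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.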

Results

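Muscle samples came from 5 female piglets, of an average body weight of 26.9 kg, in a model of the muscle weakness of intensive care. The animals were anaesthetised, ventilated and kept immobile for 5 days. They received the neuromuscular blocker pancuronium at 0.1 mg/kg/h, doses of 0.1 mg/kg of the corticosteroid betamethasone, and bacterial endotoxin at 36 µg/kg/h for 1 h. Masseter was sampled in 5 animals at day 1 (control) and at day 5 (treated). Biceps femoris had 4 arrays at each of these days, whose labels do not name the animals. The median log2 value per array lay between 6.12 and 6.16 in masseter and between 6.09 and 6.14 in biceps femoris. The series title names the question, which is how masticatory muscle is spared where limb muscle is not. Within each muscle, day 5 was compared with day 1, and the changes of the muscles were then compared with each other.

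In masseter, 58 of 73 oxidative phosphorylation genes and 11 of 26 glycolysis and glycogen genes fell by day 5, while 37 of 75 ribosomal protein genes and 14 of 30 heat shock genes rose and 3 heat shock genes fell. These lists passed with camera's preset correlation, and none passed with an estimated correlation (adjusted p = 0.344 to 0.382). AMPD3, which encodes an AMP deaminase, rose 36.2-fold, from a log2 value of 5.66 ± 0.93 to 10.84 ± 1.22 (SD, n = 5 each; change 5.18, SE 0.59, adjusted p = 0.000683). NREP, a gene named for its link to neuronal regeneration, fell from 12.92 ± 0.18 to 8.60 ± 0.92 (change -4.33, SE 0.37, adjusted p = 0.00018). RUNX1, a transcription factor known to rise in denervated muscle, rose 12.2-fold (SE of the log2 change 0.23, adjusted p = 5.36e-05), while another of its probe sets changed by 0.05 (adjusted p = 0.701). In each of these genes all 5 day 5 arrays lay on 1 side of all 5 day 1 arrays.

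Of 23999 probe sets tested in masseter, 3318 (13.8%) were called, 1755 higher and 1563 lower at day 5, and 838 of them changed at least 2-fold (413 higher, 425 lower). That fit ignores the animal, and with the animal as a block 2356 were called, 1259 higher and 1097 lower. Of these, 2161 were among the 3318. The other largest rises were those of OLFM1 (17.6-fold), TTC9 (14.2-fold), CDKN1A, a cell cycle inhibitor (13.3-fold), FOS, part of the transcription factor AP-1 (12.2-fold), CPA1 (log2 change 3.32) and ID1, an inhibitor of helix-loop-helix transcription factors (9.93-fold). The other largest falls were those of PSPHL (log2 change -3.70), MLF1 (7.71-fold), PPARGC1B, a coactivator of mitochondrial genes (7.62-fold), FAM213B (7.33-fold), PPP1R3B, which targets a phosphatase to glycogen (7.32-fold), AK1, an adenylate kinase (6.70-fold), and ITGB1BP2 (6.64-fold). Their adjusted p-values lay between 0.000152 (TTC9) and 0.0119 (AK1). The lowest day 5 array of PSPHL, at 3.76, lay near the lowest values, so its change is not exact. The count was 2138 without day 1 replicate 4 and 2047 without day 1 replicate 5. It was 4628 without day 5 replicate 1, an array with low proteasome values.

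Of 73 oxidative phosphorylation genes, 58 fell in masseter and 0 rose (65 fell and 1 rose when adjusted over the list alone), with a median change of -0.67. The list's adjusted p was 3.18e-26, and 0.344 with an estimated correlation. SDHC, a subunit of complex II, fell 2.80-fold (change -1.48, SE 0.11, adjusted p = 0.000113), and NDUFB11, of complex I, 2.14-fold (change -1.10, SE 0.09, adjusted p = 0.00018). Of 26 glycolysis and glycogen genes 11 fell (14 over the list alone; median -0.72, adjusted p = 1.86e-05, and adjusted p = 0.382 with an estimated correlation), among them TPI1 (3.04-fold) and GYS1, muscle glycogen synthase (2.84-fold). Of 30 genes of fatty acid uptake and oxidation 9 fell (11 fell and 1 rose over the list alone; median -0.29, adjusted p = 0.000487, and adjusted p = 0.344 with an estimated correlation), among them ECI1 (3.53-fold) and HADH (1.73-fold).

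Some contractile genes fell in masseter as well. Of 13 slow-fibre genes 4 fell (5 fell and 1 rose over the list alone; median -0.49, adjusted p = 0.0112, and adjusted p = 0.522 with an estimated correlation), among them MYL3, the slow ventricular myosin light chain (2.74-fold), and ATP2A2, the slow-fibre calcium pump (1.81-fold). Of 11 fast-fibre genes 3 fell (4 over the list alone; median -0.51, adjusted p = 0.00238, and adjusted p = 0.382 with an estimated correlation), among them ATP2A1, the fast-fibre calcium pump (3.15-fold), and TNNT3, fast troponin T (1.46-fold). The slow myosin MYH7 changed by -0.24 (SE 0.12, adjusted p = 0.199) and MYH4 by -1.21 (SE 0.48, adjusted p = 0.123). The MYH2 probe set lay between 3.31 and 3.59 on the masseter arrays, near their lowest values, so no change of it could be seen or excluded (change 0.05, SE 0.08, adjusted p = 0.716). MYH1, between 3.90 and 5.40 and so below the median of each array, fell by 0.66 (SE 0.18, adjusted p = 0.0315), a call lost with the animal as a block and without any 1 of 4 arrays, namely replicates 1 and 4 of day 1 (adjusted p = 0.0677 and 0.0596) and replicates 4 and 5 of day 5 (adjusted p = 0.0598 and 0.0747).

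Some genes of protein turnover and folding rose in masseter. Of 31 proteasome subunits 10 rose and 0 fell (13 rose over the list alone; median 0.63, adjusted p = 3.9e-07, and adjusted p = 0.522 with an estimated correlation), with PSMD11 up 2.11-fold and PSMC2 2.01-fold. The mean proteasome level was 10.28 on day 5 replicate 1 and between 11.44 and 11.74 on the other day 5 arrays, against 10.61 to 10.76 at day 1. Of 30 cytosolic heat shock genes 14 rose and 3 fell (17 and 4 over the list alone; median 0.73, adjusted p = 2.85e-05, and adjusted p = 0.382 with an estimated correlation). HSP90AB1 rose 2.35-fold and the co-chaperone DNAJB6 2.01-fold, while the called falls, named after their values were seen, were those of DNAJB5 (change -1.77), DNAJA4 (-1.64) and the small heat shock gene HSPB6 (-1.11). Of 75 ribosomal protein genes 37 rose and 0 fell (65 rose over the list alone; median 0.24, adjusted p = 3.86e-16, and adjusted p = 0.344 with an estimated correlation).

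Further lists moved in masseter. Of 22 endoplasmic reticulum stress genes 6 rose (8 over the list alone; median 0.48, adjusted p = 0.000487, and adjusted p = 0.382 with an estimated correlation), among them the transcription factor ATF4 (1.83-fold) and PPP1R15A (1.61-fold). Of 26 autophagy and lysosome genes 7 rose and 1 fell (10 and 1 over the list alone; median 0.23, adjusted p = 0.00641, and adjusted p = 0.344 with an estimated correlation), with GABARAP, an autophagosome protein, up 1.74-fold. Of 26 antioxidant and metallothionein genes 5 rose and 1 fell (10 and 1 over the list alone; median 0.45, adjusted p = 0.0223, and adjusted p = 0.344 with an estimated correlation), with TXN, thioredoxin, up 3.23-fold and its reductase TXNRD1 by a log2 change of 1.85. Of 27 cell cycle genes 5 fell and 1 rose (13 and 1 over the list alone; median -0.32, adjusted p = 0.000487, and adjusted p = 0.382 with an estimated correlation), with BUB1B down 2.12-fold and RRM2 1.96-fold, the latter not exact because RRM2 had low signals at day 5 (4.21 to 4.61).

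Among markers of other cells in masseter, 3 of 18 macrophage and leukocyte markers rose and 1 fell (5 and 1 over the list alone; median 0.49, adjusted p = 0.0398, and adjusted p = 0.547 with an estimated correlation), with GP91-PHOX, a subunit of the phagocyte oxidase, up by a log2 change of 1.14. The list's adjusted p was 0.0601 without day 1 replicate 1, 0.0576 without day 1 replicate 5, 0.174 without day 5 replicate 1 and 0.052 without day 5 replicate 5. Of 9 fibroblast markers 1 fell (1 over the list alone; median -0.92, adjusted p = 0.0198, and adjusted p = 0.547 with an estimated correlation), which was MFAP5 (3.43-fold). That list's adjusted p was 0.0522 without day 1 replicate 3, 0.0553 without day 5 replicate 4 and 0.052 without day 5 replicate 5. Of 41 extracellular matrix genes 2 rose and 4 fell, and the list did not pass (median -0.35, adjusted p = 0.14). It passed with the animal as a block (adjusted p = 0.0204).

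The ubiquitin ligase gene FBXO32, known as atrogin-1, rose 2.68-fold in masseter (change 1.42, SE 0.33, adjusted p = 0.0183), with all 5 day 5 arrays above all day 1 arrays. CRYAB, a small heat shock protein, rose 2.39-fold (change 1.26, SE 0.26, adjusted p = 0.0115). MSTN, which encodes myostatin, an inhibitor of muscle growth, fell by 2.09 (SE 0.52, adjusted p = 0.024), a call lost with the animal as a block. The MSTN call was also lost without day 1 replicate 2 or 5 (adjusted p = 0.0504 and 0.0629) and without day 5 replicate 2 or 4 (adjusted p = 0.0539 and 0.0505). HSPB1 changed by 0.86 (SE 0.26, adjusted p = 0.0525) and passed with a further quantile normalization (0.0371), array weights (0.0318), trend and robust settings (0.0478) or the lowest probe sets left out (0.0397). FKBP5, a glucocorticoid target, changed by 0.82 (SE 0.34, adjusted p = 0.142), IGF1 by -0.96 (SE 0.35, adjusted p = 0.0929, with array weights 0.0378) and CHRNA1, a subunit of the acetylcholine receptor, by -0.21 (SE 0.23, adjusted p = 0.599). In 1 fit of all 18 arrays the masseter calls of CRYAB (adjusted p = 0.0523), MYL3 (0.116) and PPP1R15A (0.0839) were lost, and a further quantile normalization ended that of MYH1 (0.0507). Other probe sets of OLFM1, BUB1B, TNNT3, TXNRD1 and RPL15 had changes of the opposite sign in masseter that did not pass. Further ones of RUNX1 (0.05, adjusted p = 0.701), HSP90AB1 (0.06, adjusted p = 0.866) and ATF4 (0.09, adjusted p = 0.853) lay near 0. Others of ATP2A2, BUB1B, MYH1, PSMC2 and SDHC kept the sign without passing.

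In biceps femoris, 55 of 73 oxidative phosphorylation genes, 20 of 41 matrix genes and 8 of 13 slow-fibre genes fell by day 5, while 29 of 31 proteasome genes and 63 of 75 ribosomal protein genes rose. These lists too passed with the preset correlation, and with an estimated correlation their adjusted p lay between 0.156 and 0.467. CSRP3, a protein of the sarcomere's Z-disc, fell 37.7-fold, from 12.57 ± 0.69 to 7.34 ± 1.73 (SD, n = 4 each; change -5.24, SE 0.79, adjusted p = 0.00286). NREP fell 20.1-fold, from 12.44 ± 0.22 to 8.12 ± 1.04 (change -4.33, SE 0.45, adjusted p = 0.000585). SMPDL3A rose 11.1-fold (change 3.47, SE 0.85, adjusted p = 0.025) and BLNK, an adaptor known from B cells, 10.2-fold (change 3.34, SE 0.24, adjusted p = 0.000197). In each of these genes all 4 day 5 arrays lay on 1 side of all 4 day 1 arrays.

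Of 23999 probe sets tested in biceps femoris, 4117 were called, 2373 higher and 1744 lower at day 5, and 1239 of them changed at least 2-fold (613 higher, 626 lower). The other largest rises were those of TTC9 (8.59-fold), AMPD3 (7.42-fold), HSPA2, a 70 kDa heat shock protein (7.28-fold), GPD2, the mitochondrial glycerol phosphate dehydrogenase (6.62-fold), UCHL1, a deubiquitinating enzyme (5.73-fold), and the transcription factor KLF4 (5.67-fold). The other largest falls were those of CA2, a carbonic anhydrase (14.3-fold), TNNT1, slow troponin T (14.1-fold), PPARGC1B (13.2-fold), LMCD1 (11.8-fold), MYL3 (11.5-fold) and TNNI1, slow troponin I (11.1-fold). CA2 lay between 3.20 and 3.73 at day 5, and PPARGC1B at 3.92 and 3.98 on 2 of the 4 day 5 arrays, near the lowest values of the arrays, so these folds are not exact. The AMPD3 call was lost without day 1 replicate 3 (adjusted p = 0.0526) or day 5 replicate 4 (adjusted p = 0.0506), and that of SMPDL3A without any 1 of 5 arrays (adjusted p from 0.0508 to 0.0688).

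The BioC spike-in, a control RNA added before hybridisation, set 3 day 1 arrays of biceps femoris (8.87, 8.94 and 9.13) apart from day 1 replicate 4 (7.97) and from the 4 day 5 arrays (7.43 to 7.78). Its mean was 8.73 ± 0.52 at day 1 and 7.58 ± 0.15 at day 5 (exact permutation test, two-sided, p = 0.0286). The sets were cut at the widest BioC gap. Of the other spike-in controls, Dap parted them too, by less (6.45 to 6.59 against 6.71 to 7.01). BioB (7.39 to 7.72 against 7.15 to 7.65) and Cre (12.69 to 12.74 against 12.65 to 12.99) overlapped between the sets. The 28S ribosomal RNA probe set differed between the days, from 11.85 ± 0.20 at day 1 to 12.69 ± 0.44 at day 5 without overlap (exact permutation test, two-sided, p = 0.0286). It was tested only after the data were seen, and its cause was not tested. With these sets as a block, a fit chosen after seeing the data that compares day 5 with day 1 replicate 4 within the shared set, 1306 probe sets were called, 764 higher and 542 lower. Of the 4117 calls 1128 remained, and 29 of the 47 called genes among those examined passed. Those that did not include AMPD3, ATP2A2, CHRNA1, COL1A1, CSRP3, DNAJC3, HSPA2, ISG15, KLF4, LMCD1, MYH7, MYL3, PDIA6, TNNI1, TNNT1, TOP2A and UCHL1. Their changes kept their sign, that of AMPD3 at 3.82 against 2.89 without the block, CSRP3 at -4.40, TNNT1 at -3.53 and HSPA2 at 2.08 against 2.86. With 1 day 1 array to compare, these lost calls do not show a batch effect. Since day 1 replicate 4 is also among the arrays behind the 4117 calls, values with this block are no independent test of them. The set of the 3 other arrays holds day 1 only, so it gives no value of its own. Without day 5 replicate 1, whose actin 3' minus 5' difference of 2.05 lay above the 1.04 to 1.15 of the other day 5 arrays, 4412 probe sets were called.

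Of 13 slow-fibre genes 8 fell in biceps femoris and 0 rose (10 over the list alone; median -2.09, adjusted p = 2.67e-05, and adjusted p = 0.467 with an estimated correlation). MYH7 fell 7.69-fold (change -2.94, SE 0.83, adjusted p = 0.0421) and ATP2A2 3.94-fold (change -1.98, SE 0.34, adjusted p = 0.00545). The day 5 arrays differed among themselves, with mean slow-fibre levels of 11.84, 9.11, 8.86 and 10.90 against 12.22 to 13.02 at day 1. The calls of MYH7, TNNT1 and TNNI1 were each lost without any 1 of 6 arrays and that of MYL3 without any 1 of 5, with adjusted p up to 0.0987. Those calls, and that of CSRP3, ended with the spike-in block (MYH7 change -2.73, adjusted p = 0.355), and the list had a median of -1.78 with it (adjusted p = 0.00119). None of 11 fast-fibre genes was called (median -0.10, adjusted p = 0.604). MYH4 changed by -0.16 (SE 0.24, adjusted p = 0.708). MYH1 (change -0.13, SE 0.21, adjusted p = 0.732) and MYH2 (change 0.25, SE 0.15, adjusted p = 0.32) lay below the median of each array, where changes may not show.

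Genes for other parts of the fibre and its metabolism fell too. Of 21 sarcomere and cytoskeleton scaffold genes 9 fell and 1 rose in biceps femoris (10 and 3 over the list alone; median -0.26, adjusted p = 0.00726, and adjusted p = 0.309 with an estimated correlation), with SMPX down 5.52-fold and TCAP, which caps titin, 3.48-fold. Of 73 oxidative phosphorylation genes 55 fell and 0 rose (62 and 2 over the list alone; median -0.84, adjusted p = 2.4e-24, and adjusted p = 0.426 with an estimated correlation). NDUFS1 of complex I fell 4.25-fold (change -2.09, SE 0.09, adjusted p = 9.09e-05), the smallest adjusted p of the comparison, and ATP5G3 of the ATP synthase 3.16-fold. Of 30 genes of fatty acid uptake and oxidation 11 fell (15 fell and 2 rose over the list alone; median -0.48, adjusted p = 4.36e-05, and adjusted p = 0.43 with an estimated correlation), with the fatty acid binding protein FABP3 down 7.91-fold and ECI1 5.80-fold. Of 26 glycolysis and glycogen genes 7 fell (8 over the list alone; median -0.58, adjusted p = 0.000956, and adjusted p = 0.467 with an estimated correlation), with GYS1 down 3.04-fold and PKM 3.03-fold. With the spike-in block the medians of these lists were -0.56, -0.61, -0.12 and -0.77.

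Of 41 extracellular matrix genes 20 fell in biceps femoris and 1, the protease inhibitor TIMP2, rose (24 and 1 over the list alone; median -0.82, adjusted p = 1.01e-05, and adjusted p = 0.43 with an estimated correlation). COL1A1 fell 6.23-fold, COL4A2 1.91-fold, and COL6A1 fell by 1.32 on the log2 scale. Of 9 fibroblast markers, 4 of which are not in the matrix list, 7 fell (7 over the list alone; median -1.81, adjusted p = 7.82e-05, and adjusted p = 0.43 with an estimated correlation), with MFAP5 down 8.44-fold. Of 27 interferon response genes 4 fell and 1 rose (9 and 1 over the list alone; mean change -0.99, adjusted p = 0.000279, and adjusted p = 0.612 with an estimated correlation). Their mean level was 9.14 and 8.43 on day 1 replicates 1 and 2, 7.06 and 7.76 on the other day 1 arrays and 6.82 to 7.55 at day 5. The medians of these lists were -0.73, -1.66 and -0.47 with the spike-in block.

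Proteasome genes rose in biceps femoris, 29 of 31 (30 over the list alone; median 1.09, adjusted p = 2.27e-20, and adjusted p = 0.156 with an estimated correlation), with PSMD3 up 3.35-fold and PSMC2 3.09-fold. The authors' own list of genes over 2-fold, chosen on these arrays, has 21 proteasome entries and is not independent of this count. Of 75 ribosomal protein genes 63 rose and 0 fell (68 over the list alone; median 0.46, adjusted p = 2.39e-21, and adjusted p = 0.309 with an estimated correlation), with RPL13 and RPL5 up 1.62-fold and 1.61-fold. Of 20 ubiquitin ligase and atrophy genes 4 rose and 1 fell (8 and 1 over the list alone; median 0.38, adjusted p = 0.0376, and adjusted p = 0.467 with an estimated correlation), with CDKN1A up 3.94-fold and EIF4EBP1, a repressor of translation, 2.30-fold. That list's adjusted p was 0.061, 0.0624, 0.131 and 0.0638 without day 1 replicates 2 and 4 and day 5 replicates 3 and 4. Of 26 autophagy and lysosome genes 7 rose (7 over the list alone; median 0.19, adjusted p = 0.0154, and adjusted p = 0.604 with an estimated correlation), with the protease CTSD up 2.83-fold and GABARAP 2.17-fold, and the list's adjusted p was 0.0624 without day 1 replicate 4. With a further quantile normalization neither of these 2 lists passed (adjusted p = 0.0516 each). Fitted with the spike-in block, these lists had medians of 1.02, 0.52, 0.41 and 0.31.

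Chaperone lists moved less evenly in biceps femoris. Of 30 cytosolic heat shock genes 6 rose and 2 fell (6 and 2 over the list alone; median 0.57, adjusted p = 0.012, and adjusted p = 0.722 with an estimated correlation), with HSPA2 and the co-chaperone STIP1 up 7.28-fold and 3.48-fold, and with falls of HSPB6 (change -2.18) and DNAJB5 (-2.03), named after their values were seen. Of 22 endoplasmic reticulum stress genes 4 rose and 1, ASNS, fell (4 and 1 over the list alone; median 0.48, adjusted p = 0.012, and adjusted p = 0.664 with an estimated correlation), with DNAJC3 up 2.19-fold and PDIA6 1.35-fold. Neither list passed without day 5 replicate 1 (adjusted p = 0.237 and 0.184) or with the spike-in block (medians 0.43 and 0.39, adjusted p = 0.0785 and 0.0797). Of 27 cell cycle genes 9 fell and 1 rose (15 and 1 over the list alone; median -0.40, adjusted p = 0.000231, and adjusted p = 0.467 with an estimated correlation; with the spike-in block median -0.45), with TOP2A down 3.81-fold and TPX2 2.05-fold, folds that are not exact because TOP2A (3.96 to 5.02) and TPX2 (4.42 to 4.55) had low signals at day 5.

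Among the fixed genes in biceps femoris, CHRNA1 fell by 0.72 (SE 0.18, adjusted p = 0.0256), a call lost without day 5 replicate 3 (adjusted p = 0.0627) and with the spike-in block (change -0.58, adjusted p = 0.347). FBXO32 changed by 0.78 (SE 0.53, adjusted p = 0.377), MSTN by 0.80 (SE 0.75, adjusted p = 0.54), CRYAB by 0.07 (SE 0.59, adjusted p = 0.955) and HSPB1 by 0.65 (SE 0.50, adjusted p = 0.449). IGF1 changed by -1.39 (SE 0.42, adjusted p = 0.0562, under 0.05 with a further quantile normalization, array weights, 1 fit of all arrays or the lowest probe sets left out). Other IGF1 probe sets were called, with changes of -0.44 (adjusted p = 0.0191) and -1.34 (adjusted p = 0.0424). FKBP5 changed by 0.87 (SE 0.43, adjusted p = 0.224), and by 2.12 with the spike-in block. The authors' list of genes over 2-fold gives a myostatin fold of 2.14, and the second MSTN probe set changed here by 1.10 (SE 0.79, adjusted p = 0.413). Other probe sets of NDUFS1 and COL6A1 had changes of the opposite sign in biceps femoris that did not pass, as did others of OLFM1, GPAM and OPCML for the difference between the muscles. Further ones of LMCD1 (-0.02, adjusted p = 0.897), TNNI1 (-0.21, adjusted p = 0.172), COL1A1 and COL6A1 kept the sign in biceps femoris without passing.

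**Figure D1:**
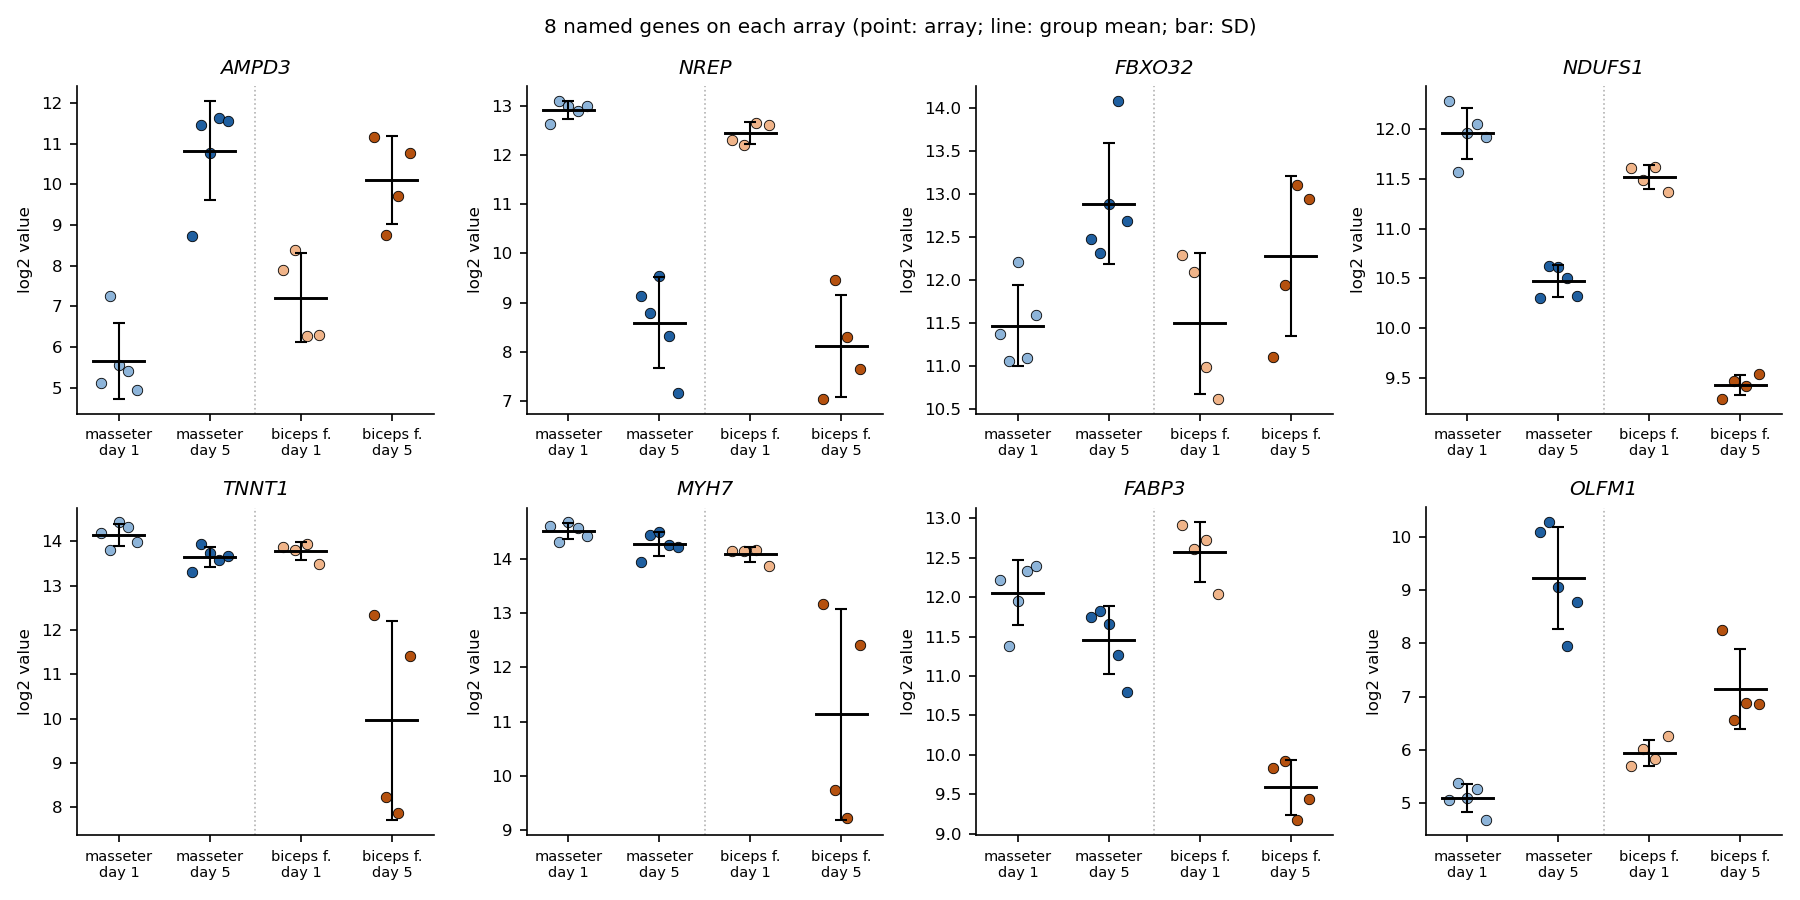
Log2 value of 8 named genes on each array, with a line at each group mean and bars of 1 SD, for 5 masseter and 4 biceps femoris arrays per day. AMPD3 rose and NREP fell in both muscles, while the day 5 arrays of biceps femoris spread widely for TNNT1 and MYH7.

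The changes of the muscles went largely the same way. Across the 23999 probe sets the log2 changes correlated with a Pearson r of 0.684 and a Spearman rho of 0.605, which have no p because probe sets are not independent. Of the calls, 1608 probe sets were called in both muscles, and 1 of them with opposite signs. Rises shared by both numbered 878, against 173.5 for independent lists of that size, and shared falls numbered 729, against 113.6. AMPD3, TTC9, NREP and PPARGC1B were among the 8 largest rises or falls of both.

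**Figure D2:**
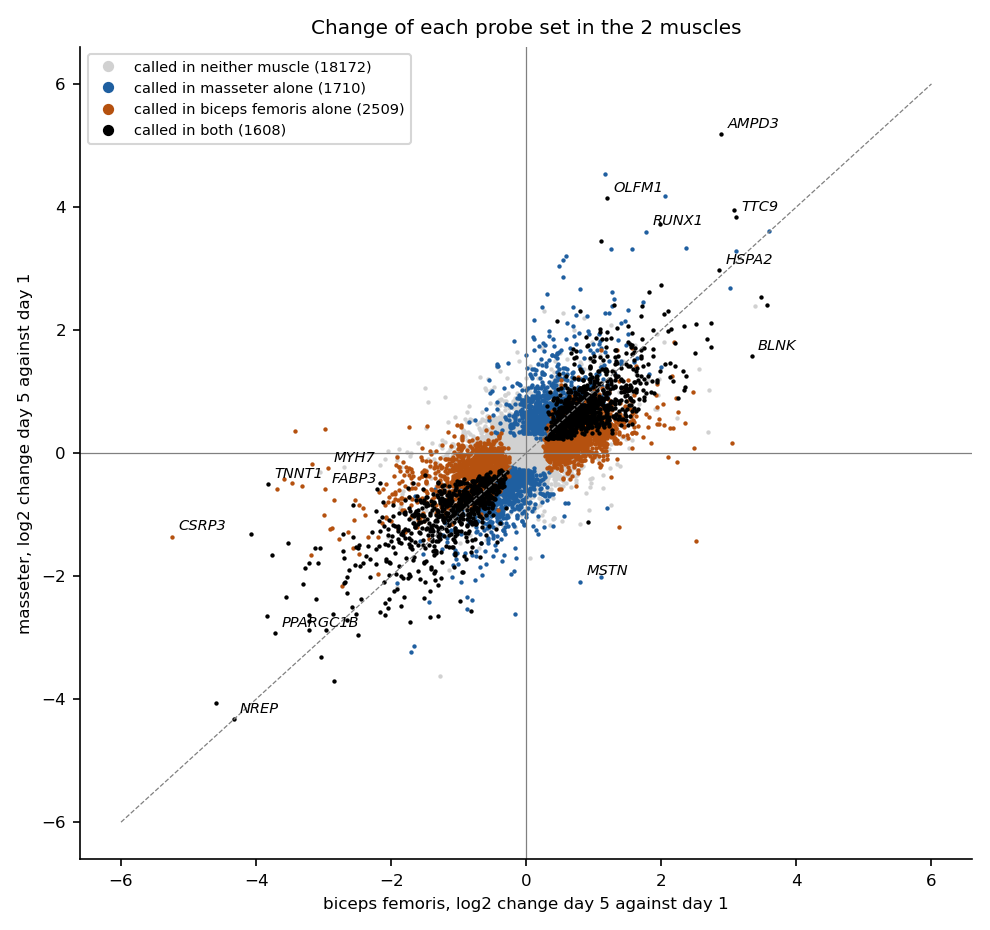
Log2 change from day 1 to day 5 of each of 23999 probe sets in biceps femoris (horizontal axis) and masseter (vertical axis), coloured by the muscles in which it was called, with a dashed line of equal change. Most of the 1608 probe sets called in both lie in the quadrants of shared sign, while TNNT1, MYH7 and FABP3 lie far below 0 in biceps femoris and nearer to 0 in masseter.

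The difference between the changes addresses the question of the title most directly, and it was called for few single genes. FABP3, which carries fatty acids in muscle cells, fell by 2.98 in biceps femoris and changed by -0.59 in masseter (difference masseter minus biceps femoris 2.39, SE 0.35, adjusted p = 0.0107). OLFM1 rose by 4.14 in masseter and by 1.20 in biceps femoris (difference 2.94, SE 0.57, adjusted p = 0.0465), and PCAF, a histone acetyltransferase, by 1.59 in masseter against a change of 0.38 (difference 1.20, SE 0.20, adjusted p = 0.0263). GPAM, an enzyme of triglyceride synthesis, fell by 2.84 in biceps femoris against a change of -0.76 in masseter (difference 2.08, SE 0.40, adjusted p = 0.0465). Other GPAM probe sets had smaller differences (-0.0012, 0.81, 0.87 and 1.02) that were not called. GCDH and MUT, mitochondrial enzymes of amino acid breakdown, had negative differences, with negative changes in masseter and small positive ones in biceps femoris. GCDH changed by -1.20 against 0.26 (difference -1.47, SE 0.21, adjusted p = 0.0107) and MUT by -0.80 against 0.24 (difference -1.04, SE 0.17, adjusted p = 0.0263).

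In all, 48 probe sets were called for the difference, 16 with a higher and 32 with a lower change in masseter, and 29 of them differed at least 2-fold. The other largest positive differences were those of ITGB6 (1.68), AHCYL1 (1.19), OPCML (0.89) and C20orf44 (0.88). The other largest negative differences were those of MAMDC2 (-1.74), ZXDC (-1.56), STRBP (-1.46), RPA3 (-1.24), ZNF79 (-1.14) and CD164 (-1.08). In masseter ITGB6 (3.00 to 3.85) and C20orf44 (3.67 to 4.08) lay near the lowest values, as did MAMDC2 in biceps femoris (3.19 to 4.66), so these 3 differences are not exact. Some of the largest changes within a muscle, such as those of CSRP3 (difference adjusted p = 0.281) and RUNX1 (0.299), were not called for the difference, nor was MSTN (difference -2.88, SE 0.95, adjusted p = 0.213). The planned replicate block in each muscle left 0 calls for the difference, though biceps femoris numbers need not name animals. With the animal as a block in masseter alone 21 probe sets were called, 17 of them among the 48. That block ended 8 of the 16 named calls, those of OLFM1, GPAM, ITGB6, C20orf44, MAMDC2, ZXDC, STRBP and RPA3. Trend and robust settings ended the calls of OLFM1, GPAM, ITGB6, OPCML, STRBP and ZXDC, and a further quantile normalization those of OPCML and ZXDC. With array weights RUNX1, TNNI1, TNNT1 and TNNT3 were among the genes called in addition. With the spike-in block 49 were called, of which 4 were among the 48. Among the 16 named genes, FABP3 and AHCYL1 were the 2 that remained called without each array and each masseter animal, and with the spike-in block GCDH and ITGB6 did. Leaving out 1 array moved the count by over 1.5 times for 14 of the 18 arrays, from 9 without biceps femoris day 5 replicate 3 to 266 without its day 5 replicate 1.

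Slow-fibre genes fell less in masseter than in biceps femoris (median difference 2.07, adjusted p = 3.07e-08, and adjusted p = 0.362 with an estimated correlation; 0 of 13 genes were called over all genes and 10 over the list alone). The difference was also positive for sarcomere and cytoskeleton scaffold genes (median 0.19, adjusted p = 0.0227, and adjusted p = 0.48 with an estimated correlation; 0 called over all genes, 3 over the list alone). Fast-fibre genes had lower changes in masseter than in biceps femoris (median difference -0.25, adjusted p = 0.00365, and adjusted p = 0.48 with an estimated correlation; 0 called either way). With the spike-in block the medians were 1.51, 0.19 and -0.15 (adjusted p = 0.000951, 0.0165 and 0.325), so the fast-fibre call ended. Scaffold genes did not pass without masseter day 5 replicate 1 (adjusted p = 0.11), masseter day 1 replicate 3 (0.0514) or biceps femoris day 1 replicate 4 (0.0519), nor without masseter animal 1 (median 0.03, adjusted p = 0.13).

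Matrix genes (median difference 0.55, adjusted p = 9.1e-05, and adjusted p = 0.48 with an estimated correlation), fibroblast markers (median 0.89, adjusted p = 0.00449, and 0.518 with an estimated correlation) and interferon response genes (median 0.91, adjusted p = 1.57e-06, and 0.48 with an estimated correlation) also had higher changes in masseter. With the spike-in block the medians were 0.32, 0.82 and 0.32, and the fibroblast markers no longer passed (adjusted p = 0.0427, 0.0641 and 0.0165). Proteasome genes rose more in biceps femoris (median difference -0.40, adjusted p = 0.000243, and 0.716 with an estimated correlation), but not without masseter day 5 replicate 1 (median -0.15, adjusted p = 0.0508) or without that animal (adjusted p = 0.0627). Ribosomal protein genes rose more there too (median difference -0.21, adjusted p = 7.69e-13, and 0.362 with an estimated correlation; with the spike-in block median -0.27, adjusted p = 2.96e-22). Oxidative phosphorylation genes had a median difference of 0.10 (adjusted p = 0.00622, and 0.825 with an estimated correlation), which turned to -0.03 with the spike-in block (adjusted p = 0.357). That list did not pass without masseter day 1 replicate 2 (adjusted p = 0.257), biceps femoris day 1 replicate 3 (0.212) or day 5 replicate 1 (0.0925), nor without masseter animal 2 (median 0.01, adjusted p = 0.456), and fibroblast markers did not without masseter animal 1 (0.0627). In each list of this comparison named here 0 genes were called over all genes. Over the list alone 3 interferon genes were higher and 1 lower, 1 oxidative phosphorylation gene higher, 1 ribosomal gene lower, and 0 in the others.

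**Figure D3:**
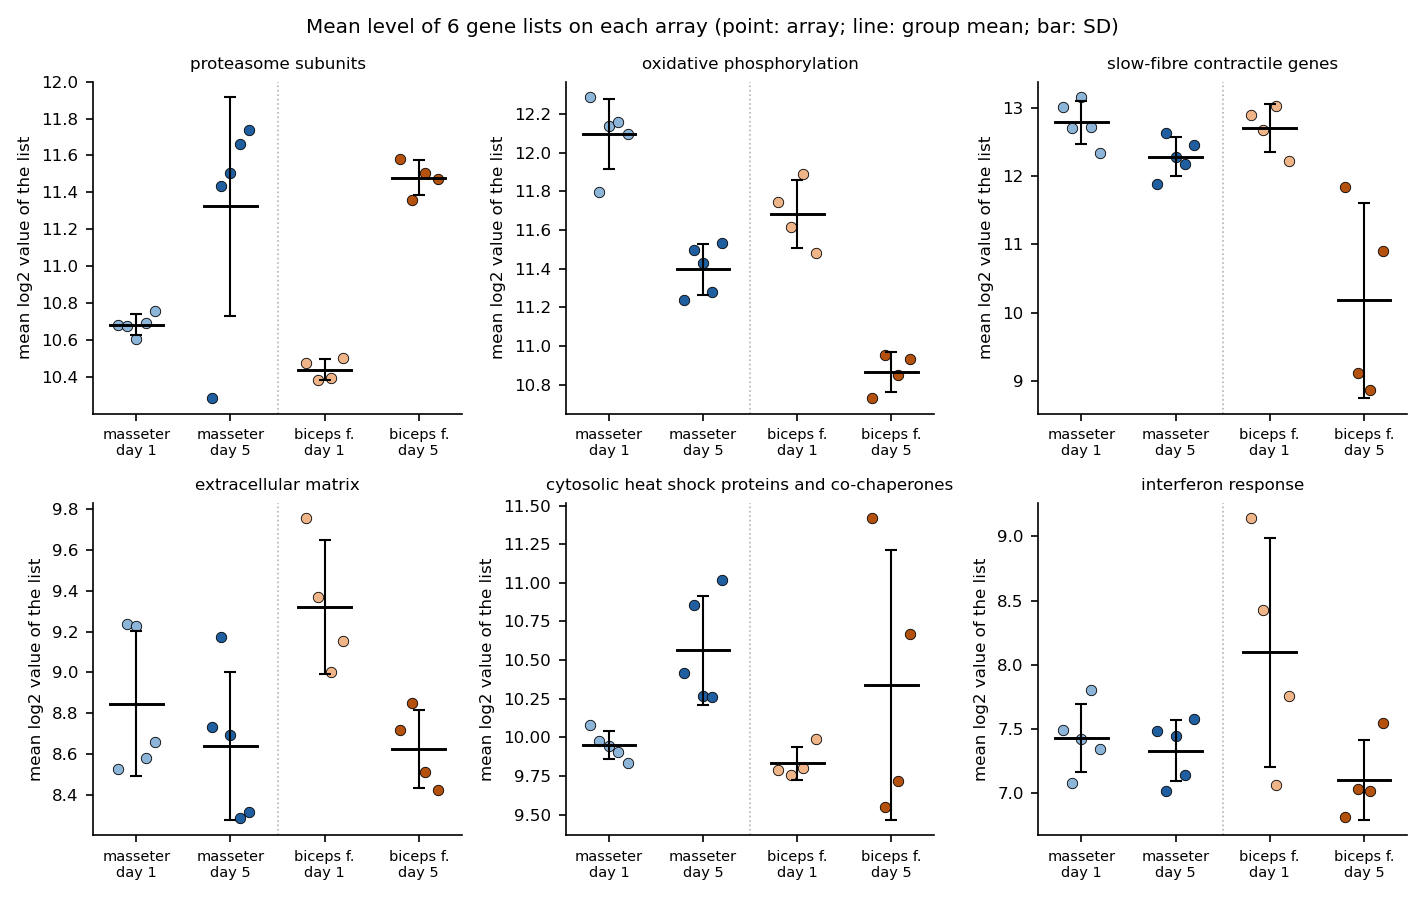
Mean log2 level of 6 gene lists on each array, with a line at each group mean and bars of 1 SD, for 5 masseter and 4 biceps femoris arrays per day; levels of the muscles were normalized apart. One masseter day 5 array lies at 10.28 for proteasome genes, below the other day 5 arrays, and the slow-fibre level of the biceps femoris day 5 arrays spans 8.86 to 11.84.

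**Figure D4:**
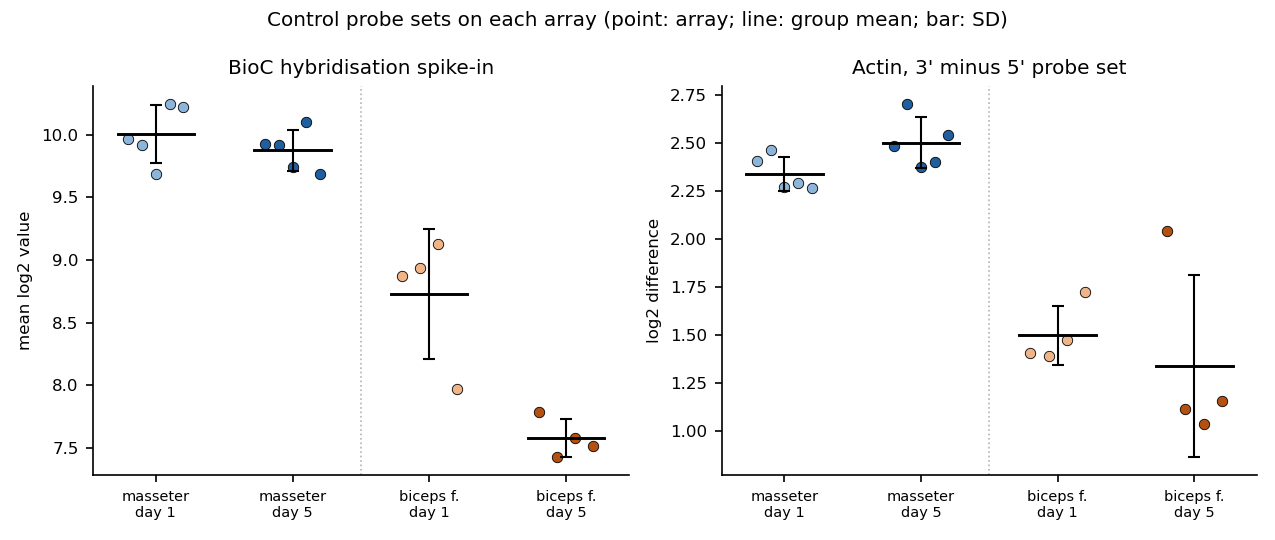
Mean log2 value of the BioC hybridisation spike-in (left) and log2 difference between the 3' and 5' actin probe sets (right) on each array, with a line at each group mean and bars of 1 SD, for 5 masseter and 4 biceps femoris arrays per day. In biceps femoris 3 day 1 arrays have BioC values of 8.87 to 9.13, the others 7.97 or less, and 1 day 5 array has an actin difference of 2.05.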

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

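Tests of the spike-in block, of the fast-fibre list as a sign of fibre share, of the connective tissue markers, of splits that part every animal, of the single masseter array and of its oxidative phosphorylation level were chosen only after the results were seen.

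Among splits of the masseter arrays, 1 of 100 gave as many calls, the real one (3318 probe sets, highest other 42). In biceps femoris 1 of 35 did (4117, highest other 1). Chance is thus argued against for both counts, though not excluded, if arrays are free to change places. The biceps femoris share cannot go below 1 of 35, and those splits do not part the treatment from the spike-in sets. As masseter numbers name animals, the splits that part every animal compare more closely. They are 16, too few for a share under 0.05, and gave 3318 calls for the real one and at most 0 for the others. For the difference between the muscles 3 of 100 splits gave as many, the real one with 48 and others with 1546 and 67. Both of these kept the days of biceps femoris apart while mixing those of masseter, so they hold the day change of biceps femoris, and splits that mix the days of both muscles put those changes into the residual spread. The splits therefore do not decide whether chance gives the 48.

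Slow-fibre genes fell more in biceps femoris than in masseter (median difference 2.07, adjusted p = 3.07e-08). Degraded RNA on biceps femoris day 5 replicate 1, the array with the high actin difference, did not make the fall. Its slow-fibre level of 11.84 was the highest of the day 5 arrays. Leaving it out could thus only enlarge the difference (camera adjusted p = 2.84e-13 without it, range over its alternatives 2.84e-13 to 0.362). Actin differences of the other day 5 arrays (1.04 to 1.15) lay below those at day 1 (1.39 to 1.72), and a part of RNA quality between the days was not tested. A hybridisation batch cannot be told apart from the treatment, because the shared set held 1 day 1 array, which the value without the block also uses (median fall with the block 0.852 times that without it). A smaller share of slow fibres in the sampled piece may also account for it, and the fast-fibre list did not decide this (adjusted p = 0.604). A loss of slow-fibre transcripts within fibres stays open as a biological hypothesis.

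Matrix genes fell more in biceps femoris than in masseter (median difference 0.55, adjusted p = 9.1e-05). That 1 masseter animal made the difference is argued against, as the highest adjusted p with an animal left out was 0.00361 (range over all alternatives 6.25e-07 to 0.48). The batch stays open for the same reason as above, with a median fall 0.894 times that without the block. Fewer connective tissue cells in the sampled piece could also account for it. The 4 fibroblast markers outside the matrix list had a median change of -1.33, but 2 of them passed, MFAP5 (-3.08) and THY1 (-2.09), and PDGFRA (0.39) and FAP (-0.57) did not.

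Proteasome genes rose more in biceps femoris than in masseter (median difference -0.40, adjusted p = 0.000243). This may rest on 1 array, since without masseter day 5 replicate 1 the adjusted p was 0.0508 (range over all alternatives 2.07e-06 to 0.716). Under both other scalings the camera adjusted p was at most 0.000403. These were applied on top of the authors' RMA values and cannot undo their normalization, so its part was not decided. Whether that array is a mislabelled day 1 array was first tested, as planned, on 4628 probe sets called without it, of which 51.1% lay nearer to the day 5 mean, which did not decide it. A second test, on 1 list and added because the first was undecided, went against it. The oxidative phosphorylation level of that array lay below the lowest day 1 array (gap -0.56, day 1 range 0.49). Its ribosomal protein (13.53, day 1 at most 13.37) and heat shock levels (10.42, day 1 at most 10.08) also lay beyond day 1. Its glycolysis (11.38, day 1 11.3 to 11.9) and scaffold levels (12.19, day 1 11.97 to 12.35) lay within day 1. Lists thus went both ways and do not decide it. A biological difference of that animal was not tested.

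Single arrays stood apart from the others of their group in 19 of 222 groups of gene values and 3 of 58 groups of list means, where chance gives about 1 in 20. Values are the gap to the nearest array as a share of the range. In masseter at day 1 these were replicate 2 for AMPD3 (0.735), ECI1 (0.800) and FKBP5 (0.788), replicate 3 for BUB1B (0.738), RRM2 (0.810) and the cell cycle mean (0.729), and replicate 4 for CPA1 (0.755). In masseter at day 5 these were replicate 1 for CDKN1A (0.716), ECI1 (0.715), NDUFB11 (0.773), RUNX1 (0.731), TTC9 (0.713) and the proteasome mean (0.793), and replicate 3 for CTSV (0.910). In biceps femoris at day 1 these were replicate 1 for CHRNA1 (0.969), replicate 2 for PDIA6 (0.940) and UCHL1 (0.922), and replicate 4 for MYH7 (0.906) and the fatty acid mean (0.977). In biceps femoris at day 5 these were replicate 1 for GPD2 (0.878) and replicate 2 for ATP5G3 (0.865) and SMPX (0.854).

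The change differed between the muscles, as masseter minus biceps femoris on the log2 scale, for OLFM1 (2.94), FABP3 (2.39), GPAM (2.08), ITGB6 (1.68), PCAF (1.20), AHCYL1 (1.19), OPCML (0.89), C20orf44 (0.88), MUT (-1.04), CD164 (-1.08), ZNF79 (-1.14), RPA3 (-1.24), STRBP (-1.46), GCDH (-1.47), ZXDC (-1.56) and MAMDC2 (-1.74). Lists that passed for the difference with camera's preset correlation were, by the median, slow-fibre (2.07), interferon (0.91), fibroblast (0.89), macrophage (0.56), matrix (0.55), smooth muscle (0.34), endothelial (0.31), growth factor (0.26), scaffold (0.19), denervation (0.17), oxidative phosphorylation (0.10), ribosomal (-0.21), fast-fibre (-0.25) and proteasome (-0.40) genes. None of them passed with an estimated correlation (adjusted p = 0.287 to 0.825), and of the 14 lists 7 passed with the spike-in block and 3 with fry.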

How the results depend on the processing

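The spike-in block and the animal block in masseter alone were chosen only after the results were seen. The planned test of masseter against biceps femoris at day 1 and its alternatives were not run, as the muscles were normalized apart. Counts called were 838 in masseter and 1239 in biceps femoris with a 2-fold minimum, which is stricter by construction, and 1306 in biceps femoris with the spike-in block. Without each array in turn masseter gave 2047 to 4628 calls and biceps femoris 2951 to 4412. For the difference, 24 probe sets were called with trend and robust settings, 527 with array weights, 29 with a 2-fold minimum, 21 with the animal block in masseter, and 0 with the replicate block in limma (2800 at an unadjusted p under 0.05), where biceps femoris numbers need not name animals. With that block biceps femoris gave 3041 calls, CHRNA1, MYH7 and MYL3 no longer passed, and no biceps femoris array correlated best with its own number. In masseter the animal block ended the calls of CD53, MSTN and MYH1, matrix genes passed, and no other named call or list changed. Without each array or animal the difference between the muscles gave 3 to 266 calls, the lowest without masseter animal 5. With camera's estimated correlation 0 lists passed in masseter, 0 in biceps femoris and 0 for the difference. With fry, which asks only whether a list's genes move 1 way, calls were lost in masseter for proteasome (adjusted p = 0.0885), macrophage (0.097) and fibroblast genes (0.105), and in biceps femoris for interferon (0.119), heat shock and endoplasmic reticulum stress genes (0.15 each). Calls were gained for denervation (0.00795) and growth factor genes (0.049) in masseter and smooth muscle markers (0.0312) in biceps femoris. For the difference, 3 of 14 lists passed with fry, 7 with the spike-in block, and 6 to 14 without each array or animal, the fewest without masseter animal 1. With the spike-in block the oxidative phosphorylation difference turned to -0.0341. Other probe sets of a gene had the opposite sign, none passing, in masseter for BUB1B (0.20), OLFM1 (-0.0865), RPL15 (-0.0535), TNNT3 (0.35) and TXNRD1 (-0.18), in biceps femoris for COL6A1 (0.17), ISG15 (-1.62) and NDUFS1 (1.11), and for the difference for GPAM (change -0.0012), OLFM1 (-0.0126) and OPCML (-0.25). Of the other probe sets of named called genes, 18 of 33 gave the same direction and call in masseter, 16 of 26 in biceps femoris and 1 of 12 for the difference. These count probe sets, and some genes have several. Except for the constructions named, the cause was not tested. Without each array, 44 of 47 named calls in masseter, 40 of 47 in biceps femoris and, with animals, 2 of 16 for the difference remained. Both other scalings left the total counts of probe sets and lists within 1.5 times, but with median centring 49 differences were lower in masseter against 32. The correlation of the muscles was 0.615 to 0.714 without each array. Arrays limit low signals, which lie near background.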

Other observations

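Glucocorticoid-responsive genes, and acute phase and cytokine genes, were lists matched to the betamethasone and endotoxin given, and neither passed in masseter (medians 0.29 and 0.07, adjusted p = 0.239 and 0.418) or in biceps femoris (medians -0.02 and 0.03, adjusted p = 0.774 and 0.943). Of 27 glucocorticoid-responsive genes 3 rose and 1 fell in masseter, and 1 rose in biceps femoris. For the difference their adjusted p was 0.567 each. Denervation and junction genes did not pass in masseter (adjusted p = 0.215) or biceps femoris (0.774), nor did growth factor genes (0.411 and 0.816). Their differences between the muscles had medians of 0.17 and 0.26 (adjusted p = 0.0265 and 0.0473, and adjusted p = 0.287 each with an estimated correlation). Neither passed with the mean of a gene's probe sets (adjusted p = 0.058 and 0.171). The denervation difference was lost without masseter day 1 replicate 3 (0.0546), masseter day 5 replicate 1 (0.0508), biceps femoris day 5 replicate 4 (0.0561) or masseter animals 1, 3 or 5 (0.0604 to 0.0633). The growth factor difference was lost with the spike-in block (0.0688) and without most single arrays (0.0506 to 0.0965).

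Among the remaining lists in masseter, adjusted p was 0.411 for ubiquitin ligase and atrophy genes, 0.179 for scaffold genes and 0.297 for interferon response genes. In biceps femoris it was 0.192 for antioxidants, of which 6 rose and 5 fell. Macrophage markers did not pass in biceps femoris (median -0.05, adjusted p = 0.729), and their difference between the muscles (median 0.56, adjusted p = 0.00567, and 0.48 with an estimated correlation) had an adjusted p of 0.0508 without masseter day 5 replicate 1, 0.0817 without that animal and 0.619 with the spike-in block. Endothelial (0.776 and 0.0917), smooth muscle (0.619 and 0.054), adipocyte (0.908 and 0.946), nerve (0.821 and 0.816) and erythrocyte markers (0.908 and 0.723) did not pass in masseter or biceps femoris. For the difference, endothelial markers had a median of 0.31 (adjusted p = 0.0241, and 0.549 with an estimated correlation) and smooth muscle markers 0.34 (adjusted p = 0.0319, and 0.48 with an estimated correlation). Both lost their call without several single arrays, among them masseter day 5 replicate 1 (adjusted p = 0.0815 and 0.092), without masseter animal 1 (0.0817 and 0.102) or 2 (0.197 and 0.125), and with the spike-in block (0.227 and 0.104). The endothelial difference was also lost with the mean of a gene's probe sets (0.297). In biceps femoris smooth muscle markers passed with a further quantile normalization (adjusted p = 0.0279), median centring (0.0468) or that mean (0.0377), and endothelial markers with the quantile normalization (0.0451).

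For the difference the other lists did not pass, namely ubiquitin ligase and atrophy (adjusted p = 0.567), autophagy (0.95), heat shock (0.577), endoplasmic reticulum stress (0.95), glycolysis (0.586), fatty acid (0.203), cell cycle (0.586), antioxidant (0.356), adipocyte (0.849), nerve (0.849) and erythrocyte genes (0.567). Median, mean and test differed in sign for endothelial, adipocyte and erythrocyte markers in masseter, for denervation and glucocorticoid-responsive genes, adipocyte and nerve markers in biceps femoris, and for autophagy genes, adipocyte and nerve markers in the difference. None of these passed.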
